A study of Caenorhabditis elegans with 2 samples.

How the data were processed

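ChIP-seq peak lists of 1 group, eGFP-tagged NHR-6 in L4 larvae, were analysed, with 2 biological replicates named as such in the labels. Per the labels, the worms were whole animals of strain OP90 with the sexes pooled. The deposited text listings that accompany the libraries state the file formats, the builds and which file each was derived from. Per those deposited listings, the authors called a relaxed list of peaks and background for each replicate against a control alignment, a relaxed list on the alignments of both replicates, and from these a list thresholded by the irreproducible discovery rate (IDR), in builds ce10 and ce11. The aligner, the peak caller and their settings are not given in the sources used here. The control library and the signal tracks were not analysed here.

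Each deposited peak has a signal value, a −log10 q-value and a summit offset, in the column order of the narrowPeak format. The signal value is the authors' own value per peak; its scale is not given in the sources used here, and values of separate lists are not shown to be comparable, so each list's values were used only to describe, rank and filter peaks within it, apart from the correlation between replicates. The deposited −log10 q-value reached its maximum of 3.91 in 4093 pooled ce11 peaks and in all 2720 thresholded ones, so it could not rank them. The thresholded ce11 list was identical to the 2720 pooled peaks of highest signal. Its 4 entries over egl-5 share 1 interval, which leaves 2717 distinct intervals. The relaxed peaks have nearly fixed widths (median 304, 320 and 316 bp for replicate 1, replicate 2 and the pooled list), so the number of overlaps depends on those widths. The pooled list and that of replicate 2 stop at 30000 peaks. Read depth is unknown, and intervals given for shares cover counting of peaks or genes only.

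Gene positions came from the Ensembl release 115 annotation of WBcel235, whose chromosome lengths hold every ce11 peak on the nuclear chromosomes, and only ce11 lists were set against it. No coordinates were converted, and ce10 lists were compared only with each other. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9. A promoter window ran from 1000 bp upstream to 200 bp downstream of the annotated 5′ end of a protein-coding gene. Replicates were compared over their 2720 strongest peaks on the nuclear chromosomes, counting an overlap of 1 bp. Observed shares were set against 1000 sets of positions shuffled within chromosomes, two-sided. Where a peak overlapped several peaks of another list, the one with the nearest summit was taken. Correlation intervals came from 1000 bootstrap resamples of 1 Mb bins. Shuffling ignores how well reads map, so it does not model sequence that short reads cannot reach.

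Motifs were sought on both strands within 50 bp of the summit and in windows of the same size centred 300 bp to each side, with exact McNemar tests, and a motif was called on the larger p of the sides. The 23 fixed motifs hold 22 distinct sites, because the forkhead and DAF-16 sites are reverse complements of each other. Gene lists were compared with all other protein-coding genes by Fisher's exact test, chromosome densities by exact binomial tests, and p was adjusted by Benjamini-Hochberg within each family. Tests run across peaks or genes, which are not replicates, and neighbouring genes can share a peak. On simulated data, 1 of 100 unenriched sets of 2720 positions was called for promoter share. Those sets were shuffled as the null sets are, so this checks the calculation alone. All 100 of 100 raised gene lists were recovered among 19973 genes, and with none raised 1 list was called over 20 runs. The raised lists held 38 to 274 genes and had a strong planted rise, so recovery of smaller lists or weaker rises was not measured.

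The main tests, the lists, the motifs and most alternatives were fixed before the data were examined. The alternatives added afterwards were the peaks without the egl-5 region, genes matched on promoter GC content, sites of the same base composition, and all pooled peaks at the highest q. Further tests in the closing sections were chosen later, as stated there. The genes named were nhr-6, the 25 protein-coding genes with the strongest promoter peaks, the 4 members of highest signal in each list past an adjusted p of 0.05, and the same for the spermatheca, nuclear receptor and pan-neuronal lists whether or not they passed. Any other gene was named after its values were seen. The alternatives changed the overlap rule, the number of peaks, the promoter and motif windows, the background, the length measure and the build, and used each replicate alone.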

Results

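Binding of NHR-6 to the Caenorhabditis elegans genome was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole worms at the L4 larval stage, with the sexes mixed. NHR-6 is the worm member of the NR4A family of nuclear receptors. The strain, OP90, carries an integrated transgene with an eGFP-tagged copy of nhr-6. There was 1 group with 2 biological replicates, so the design allows a comparison of the replicates and a description of where peaks lie, and no comparison of conditions. In build ce11 the relaxed list of replicate 1 held 26801 peaks, that of replicate 2 held 30000 and that of the pooled replicates held 30000. The list thresholded for reproducibility held 2720 peaks. Read depth is unknown from peak lists, so the error that depth gives to a single peak could not be stated.

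The replicates shared most, but not all, of their strongest peaks. Of the 2720 strongest peaks of replicate 1, 1556 overlapped one of the 2720 strongest of replicate 2, a share of 57.2% (Wilson 95% interval 55.3 to 59.1%), against a mean of 1.71% for sets shuffled within chromosomes (permutation test with 1000 shuffled sets, two-sided p = 0.0020, the smallest they can give). The reverse share was 57.3%. The thresholded list was made from these same replicates, so a high overlap of its peaks with their relaxed lists follows from its making. Of the 2720 thresholded peaks, 98.9% overlapped some relaxed peak of replicate 1 and 99.6% some relaxed peak of replicate 2. Fewer were among the 2720 strongest of each replicate, 74.8% (73.1 to 76.4%) for replicate 1 and 75.2% (73.6 to 76.8%) for replicate 2, and 143 were among the strongest of neither.

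Across 2681 thresholded peaks matched in both replicates, the log2 signal values of the replicates were weakly correlated, with Spearman's rho of 0.28 (95% bootstrap interval over 1 Mb bins 0.23 to 0.32) and Pearson's r of 0.30 (0.23 to 0.38). These are correlations across peaks, which are not independent replicates. The thresholded list consists of the 2720 pooled peaks of highest signal, a selection that leaves out peaks weak in both replicates, and over 12373 matched relaxed peaks rho was 0.51.

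**Figure D1:**
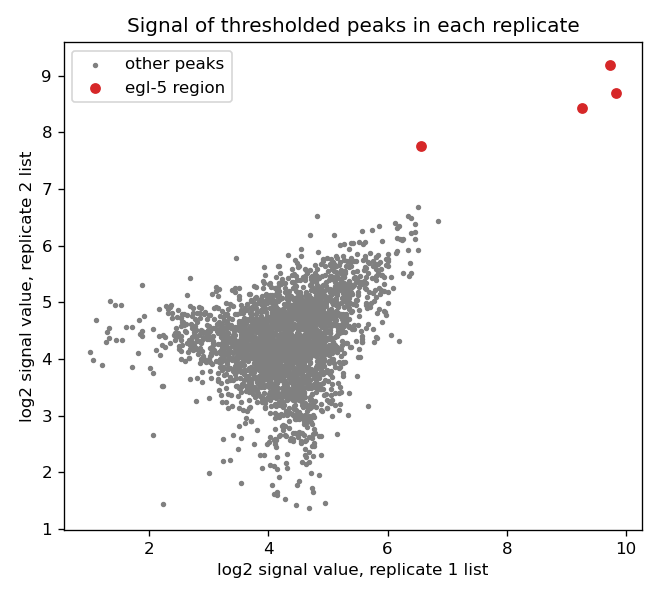
Log2 signal value of each matched thresholded peak in the list of replicate 1 (x axis) and of replicate 2 (y axis). Each point is 1 of 2681 peaks, and the 4 red points, at the upper right, are the summits in the region over egl-5.

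Most peaks lay near annotated 5′ ends of genes. Of the 2720 thresholded summits, 1568 (57.6%, Wilson 95% interval 55.8 to 59.5%) fell in the window from 1000 bp upstream to 200 bp downstream of the annotated 5′ end of a protein-coding gene. Shuffled sets gave 21.3% ± 0.789 (SD over 1000 sets), a 2.70-fold difference (permutation test, two-sided p = 0.0020). The median distance from a summit to the nearest annotated 5′ end was 472 bp, against 1626 bp in shuffled sets (permutation p = 0.0020). Pooled relaxed peaks outside the thresholded list had 26.7% of their summits in these windows (7223 of 27019). With a window of 500 bp upstream to 100 bp downstream the fold was 4.32, and with one of 2000 bp upstream to 200 bp downstream it was 1.88. Annotated 5′ ends of trans-spliced genes can lie away from the start of transcription, and 526 peaks lay in the windows of more than 1 gene.

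Intergenic sequence held 66.2% of summits, 2.00 times the shuffled share of 33.04%. Annotated 5′ untranslated regions held 4.19%, 2.36 times the shuffled share. Noncoding genes outside protein-coding genes held 6.47%, 1.64 times. Where classes overlapped, 5′ untranslated regions were taken first, then coding exons, 3′ untranslated regions, introns and noncoding genes. A noncoding gene within an intron therefore counted as intron. Coding exons held 39 summits (1.43%) where shuffled sets placed 24.3%. Introns held 20.4% against 33.6%, and 3′ untranslated regions 1.32% against 3.34%. Each class differed from the shuffled sets (permutation test, adjusted p = 0.0020, the smallest they can give). The 3′ untranslated regions stood at 0.396 of the shuffled share in the thresholded list and at 0.682 in the strongest peaks of replicate 1 alone. The coding exons stood at 0.0590 of it in the thresholded list, at 0.115 in replicate 1 alone and at 0.109 in replicate 2 alone.

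The gene lists differed widely in how many of their genes carried a promoter peak. Ribosomal protein genes, which encode the structural proteins of the cytosolic ribosome, carried a promoter peak in 66 of 81 cases (81.5%, Wilson 95% interval 71.7 to 88.4%), against 10.2% of other protein-coding genes. Proteasome subunit genes carried one in 19 of 33 cases (57.6%), genes of the mitochondrial respiratory chain in 15 of 37 (40.5%), V-ATPase subunit genes in 7 of 21 (33.3%), heat shock and chaperone genes in 19 of 61 (31.1%) and bZIP transcription factor genes in 8 of 28 (28.6%). By Fisher's exact test, two-sided and adjusted over 34 lists, the values of p were 5.57e-49 for ribosomal proteins, 5.07e-10 for the proteasome, 1.66e-05 for the respiratory chain, 4.37e-05 for chaperones, 0.0122 for the V-ATPase and 0.0173 for bZIP factors. Altogether 2097 of 19973 protein-coding genes (10.5%) had a promoter peak.

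Among ribosomal protein genes, rpl-3 had a peak of signal 167.8 (rank 7 of the thresholded list), rpl-15 one of 162.1, rps-12 one of 144.7 and rpl-35 one of 142.2. The proteasome genes rpt-1 and rpn-3 had signals of 114.9 and 82.2, followed by pbs-3 with 57.4 and rpn-8 with 54.1. In the respiratory chain, atp-1, which encodes a subunit of ATP synthase, had a signal of 101.7, ucr-2.2 one of 65.7, cox-14 one of 60.1 and nuo-1, of complex I, one of 56.4. The chaperone genes were led by cct-1 with 111.3, hsp-60 with 101.6, hsp-3 with 90.1 and hsp-110 with 82.2, and hsp-110 and rpn-3 share their peak. Of the V-ATPase genes vha-13 had 105.97, vha-14 had 93.7, vha-1 had 67.7 and vha-12 had 60.9. The bZIP genes atfs-1 and xbp-1, which act in the mitochondrial and endoplasmic reticulum unfolded protein responses, had signals of 103.6 and 67.9, cebp-1 had 85.1 and jun-1 had 74.7. The V-ATPase list had an adjusted permutation p of 0.0638 when genes were matched on the length of their upstream region (0.00195 to 0.0638 over its exact and permutation alternatives), with a fold of 2.64 (1.36 to 4.33) against 3.18 (1.64 to 5.21) over all other genes. The bZIP list had one of 0.0544 when they were matched on promoter GC content (0.00337 to 0.0544), with a fold of 2.51 (1.34 to 4.13) against 2.73 (1.46 to 4.49). The ranges of these folds come from the Wilson intervals of the shares. Folds before and after matching share the same count of genes with a peak, so the ranges do not show whether matching changed them.

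7 lists had fewer promoter peaks than other genes. Chemoreceptor genes carried a peak in 13 of 1310 cases (0.992%), neuropeptide genes in 1 of 145, homeobox genes in 1 of 94, hedgehog-related and patched genes in 1 of 85, C-type lectin genes in 7 of 240, cuticle collagen genes in 6 of 176 and F-box genes in 11 of 322. The adjusted p by Fisher's exact test was 1.43e-45 for chemoreceptors, 2.07e-05 for neuropeptides and for F-box genes, 7.22e-05 for lectins, 0.00221 for homeobox genes, 0.00260 for collagens and 0.00610 for the hedgehog-related genes. The members with peaks included ceh-38 (signal 86.9), ins-39 (70.4), wrt-3 (33.8), the chemoreceptor genes srh-16 (95.7), sri-5 (56.8), srz-62 (52.3) and srh-89 (48.4), the collagen genes col-38 (66.5), col-2 (57.998), bli-6 (43.2) and col-185 (40.9), the lectin genes clec-265 (54.96), clec-4 (44.7), clec-53 (41.9) and clec-78 (35.9), and the F-box genes fbxa-90 (81.6), fbxb-72 (77.6), fbxb-85 (72.8) and fbxa-74 (62.1). The col-185 summit lay inside a tRNA gene and the wrt-3 summit within 200 bp of a snoRNA gene. In the relaxed list of replicate 1 the wrt-3 and clec-78 peaks ranked only 5453 and 9683. By Fisher's exact test the homeobox list did not pass among the 1360 strongest peaks (odds ratio 0.166, adjusted p = 0.105) or without replicate 1 (odds ratio 0.403 against 0.0912, adjusted p = 0.169). Its adjusted p ran from 0.000755 to 0.169 over its exact and permutation alternatives. Also by the exact test, collagens did not pass among the 1360 strongest (odds ratio 0.358 against 0.299, adjusted p = 0.0896, range 0.000145 to 0.0896), nor hedgehog-related genes without replicate 1 (odds ratio 0.331 against 0.101, adjusted p = 0.109, range 0.000749 to 0.109).

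The remaining lists did not pass with the thresholded peaks and the main window. Of the spermatheca and ovulation genes, the tissue list chosen for NHR-6, 2 of 26 had a promoter peak (7.69%, adjusted p = 1 by Fisher's exact test): rga-1 with a signal of 39.5 and let-413 with 37.1. Nuclear receptor genes had one in 20 of 274 cases (7.30%, exact adjusted p = 0.193), led by nhr-50 (78.3), nhr-142 (71.8), nhr-207 (61.1) and nhr-154 (56.2). Pan-neuronal genes had one in 7 of 43 cases (16.3%, exact adjusted p = 0.358), led by unc-76 (63.8), unc-14 (63.2), unc-16 (48.9) and tom-1 (46.1). Core histone genes had one in 15 of 80 (18.8%, odds ratio 1.97, exact adjusted p = 0.0627). They passed without replicate 1 (odds ratio 2.28, exact adjusted p = 0.0200) and with the windows from 500 bp (2.51, 0.0130) and 2000 bp upstream (2.29, 0.00678). They did not pass without replicate 2 (odds ratio 1.29, exact adjusted p = 0.690) or when matched on upstream length (fold 1.08, permutation adjusted p = 0.917). Cytochrome P450 genes had a promoter peak in 4 of 74 cases (odds ratio 0.486, exact adjusted p = 0.329). In the strongest peaks of each replicate alone the odds ratio was 0.124 in replicate 2 and 0.123 in replicate 1, past the threshold (exact adjusted p = 0.0247 and 0.0147), while over all alternatives p ran to 0.690. No other list that had not passed did so under an alternative.

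**Figure D2:**
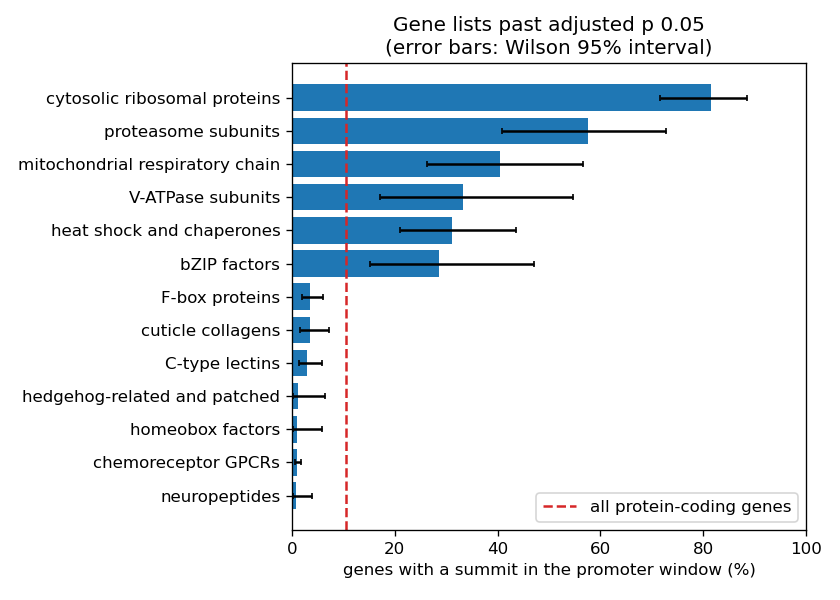
Share of genes with a thresholded summit in the promoter window (x axis, percent) for the 13 lists past an adjusted p of 0.05, with Wilson 95% intervals; the dashed line is the share of all protein-coding genes, 10.5%. The 6 lists above the line run from 28.6% to 81.5%, and the 7 below it from 0.690% to 3.42%.

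The strongest promoter peak, with a signal of 199.2, lay 725 bp upstream of T24E12.13 (WBGene00195077) on chromosome II at 3786628 to 3786836 in intergenic sequence. It ranked 15 in the relaxed list of replicate 1, mitochondrial peaks included, and 9 in that of replicate 2. The peak 157 bp upstream of cdc-48.1 (WBGene00007352), which encodes an AAA ATPase of protein degradation, had a signal of 193.1 (chromosome II, 10563472 to 10563682, intergenic) and ranked 21 and 5. That of rpl-3 (WBGene00004414) lay 288 bp upstream on chromosome III at 3867450 to 3867693 and ranked 25 and 11. The other genes among the 25 with the strongest promoter peaks were tasp-1 and K01G5.10, which share a peak of 167.7, rpl-15 and K11H12.8 (162.1), cept-2 (161.0), puf-9 (160.1), tomm-20 (158.8), pqn-92 (151.6), cyn-3 (148.9), rps-12 and ska-3 (144.7), C47E8.4 (144.5), wwp-1 (142.9), rpl-35 (142.2), C01G10.7 and ahsa-1 (142.2), R04F11.2 and R04F11.5 (136.8), hsr-9 and rps-19 (130.8), and rpl-20 and Y17G9B.5 (129.9). Signal values are the authors' own and are used within each list.

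The NR4A monomer site, AAAGGTCA, was rare at summits. It lay within 50 bp of 20 of 2720 summits (0.735%, Wilson 95% interval 0.476 to 1.13%), against 0.184% in the left flanks and 0.331% in the right flanks of the same peaks, centred 300 bp away. The share was 2.86 times the mean of the flanks, and the exact McNemar test, two-sided, gave p = 0.00408 against the left flank and p = 0.0614 against the right. By the larger of these the site did not pass the threshold. The 6-base core AGGTCA, a nuclear receptor site, was at 3.71% of summits against 2.21% of flanks (exact McNemar p = 0.00247, adjusted 0.00379). Of 180 sites with the same base composition as the core, 25 had a higher ratio of summits to flanks, so the core did not stand apart from them, a comparison chosen after the values had been seen. The 8-base site passed in the strongest peaks of each replicate alone (exact p = 0.00592 in replicate 2 and 0.00700 in replicate 1), so the call depended on the list, and over all alternatives tried p ran from 0.000156 to 1 and the ratio from 1.49, against relaxed peaks outside the list, to 4.36. By signal, the site was at 8 of the 680 strongest and 3 of the 680 weakest peaks (Fisher's exact p = 0.225).

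Other sequences differed between summits and flanks by more percentage points. GAGAGA repeats were at 27.3% of summits against 6.07% of flanks, the AP-1 site at 4.34% against 0.901%, the Sp1 GC box at 5.48% against 1.27% and CCCTC at 16.2% against 6.42%. Homeodomain sites (1.62% against 5.66%), the heat shock element (2.50% against 6.40%) and the TATA box (4.56% against 12.2%) were less frequent at summits. The adjusted p by exact McNemar tests was 7.44e-98 for GAGAGA, 4.60e-15 for AP-1, 2.91e-16 for the GC box, 4.77e-27 for CCCTC, 7.33e-15 for homeodomain sites, 4.51e-10 for the heat shock element and 9.40e-22 for the TATA box. Further fixed sites also had an adjusted p under 0.05 by this test. TGACG was at 19.6% of summits against 10.1% of flanks, CACGTG at 3.86% against 1.67% and CAGCTG at 3.68% against 1.56%. The forkhead and DAF-16 site was at 3.16% against 1.45%, CTCCGCC at 2.87% against 0.938% and CCAAT at 15.7% against 19.3%. GC content was 45.3% ± 7.88 (SD, n = 2720) at summits and 34.9% ± 6.16 in flanks. A site rich in G and C, or in A and T, can therefore differ through composition alone. The sites in this paragraph were not ranked against others of the same composition.

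Of 2080 6-mers, 644 were more frequent at summits and 478 less frequent past an adjusted p of 0.05 by the exact McNemar test. The 10 with the highest odds among those at 5% or more of summits were GACGCA (odds ratio 10.5, at 16.5% of summits), GCGCGC (10.3), AGCGCG (9.40), ACGCAG (9.12), CGCGCG (8.70), ACGCGC (8.38), GAGCGC (8.20), CGTCTC (8.02, at 19.04% of summits), AGACGC (7.59) and GCGCAC (7.40).

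**Figure D3:**
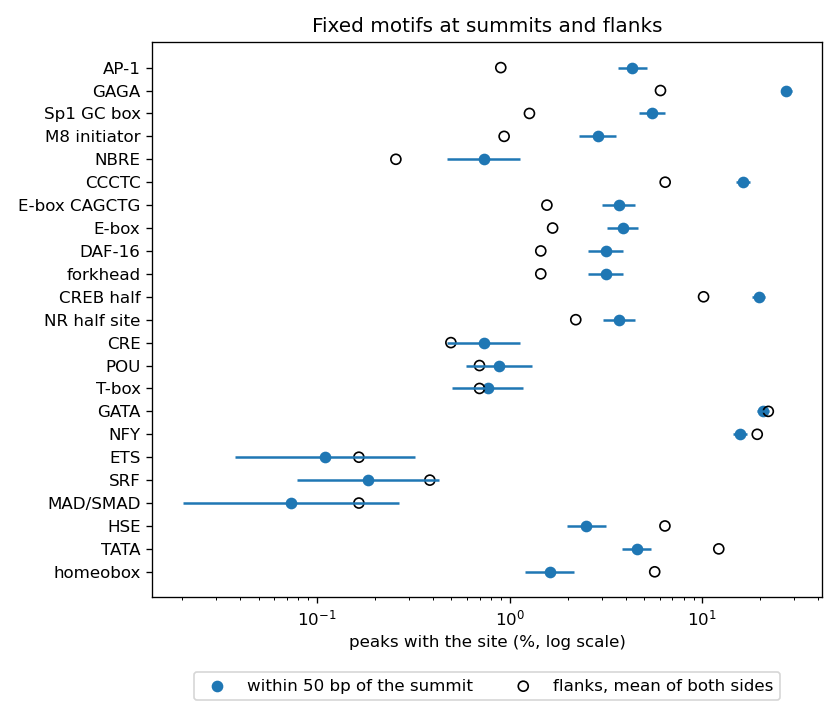
Percent of the 2720 peaks with each of 23 fixed sites (x axis, log scale) within 50 bp of the summit (filled, with Wilson 95% intervals) and in the flanks (open, mean of both sides). GAGAGA stands at 27.3% against 6.07%, and NBRE, the NR4A monomer site, at 0.735% against 0.257%.

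Small noncoding RNA genes often had a peak nearby. A summit lay within 200 bp of 123 of 612 tRNA genes (20.1%, against 1.30% in shuffled sets), 74 of 346 snoRNA genes (21.4% against 1.52%) and 15 of 129 snRNA genes (11.6% against 1.37%). Genes of the class annotated as ncRNA had one in 501 of 7764 cases (6.45% against 1.502%) and miRNA genes in 11 of 261 (4.21% against 1.33%). Pseudogenes (0.517% against 4.85%) and piRNA genes (0.260% against 0.938%) had fewer than shuffled sets. The adjusted p was 0.00333 for tRNA, snoRNA, snRNA, ncRNA, piRNA and pseudogenes and 0.0228 for miRNA (permutation test, two-sided, adjusted over the classes). lincRNA genes (15 of 194, permutation adjusted p = 0.0624), antisense RNA genes (3 of 100, permutation adjusted p = 1) and rRNA genes (0 of 20) did not pass. Without replicate 1, lincRNA genes passed (fold 1.86 against 1.77, permutation adjusted p = 0.0225, range 0.0225 to 0.608). Among the 1360 strongest peaks, miRNA genes did not pass (fold 3.12 against 3.17, permutation adjusted p = 0.103, range 0.00856 to 0.103) and the tRNA fold was 10.3 against 15.5. The shuffled sets were not matched to the 2.00-fold excess of summits in intergenic sequence, which the lincRNA folds given here did not exceed. No other factor or untagged strain was analysed here, so whether peaks near these genes depend on NHR-6 was not tested.

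Peak density differed along the autosomes. The middle parts of the autosomes, in a division of each into 3 equal parts, held 35.5 peaks per Mb and the outer parts 22.5, a ratio of 1.58 (exact binomial p = 8.92e-26, n = 2217 peaks). Counted per protein-coding gene the ratio was 1.28 (exact binomial p = 9.76e-09). Chromosome III held 32.6 peaks per Mb and IV held 22.1, a difference that was not tested. The X chromosome held 28.4 per Mb and the autosomes 26.9 (ratio 1.06, exact binomial p = 0.258). Per protein-coding gene, X stood 1.43 times higher than the autosomes (exact binomial p = 2.65e-12), while among the 1360 strongest peaks by length p was 0.803.

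The nhr-6 gene itself (WBGene00003605, chromosome III, 3573581 to 3578771, plus strand) had 3 thresholded peaks within 20 kb. The strongest, with a signal of 53.9 and rank 600 of 2720, had its summit at 3574804 in an intron of nhr-6, 1223 bp after the start of the gene. The other summits, with signals of 31.6 (rank 2108) and 31.5 (rank 2133), were intergenic, at -1869 and -3293 bp from the start of the gene. No thresholded summit lay in the promoter window of nhr-6. The strongest relaxed pooled summit there, at -951 bp, narrowly missed the list. It had a signal of 26.1 (rank 2975), against 27.5 for the weakest thresholded peak. Relaxed peaks within 20 kb numbered 18 in replicate 1, 19 in replicate 2 and 19 in the pooled list, and the last pooled summit on the downstream side before 3604400 was the one in the intron. The transgene of the strain holds nhr-6 sequence, which can add reads at the native locus.

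**Figure D4:**
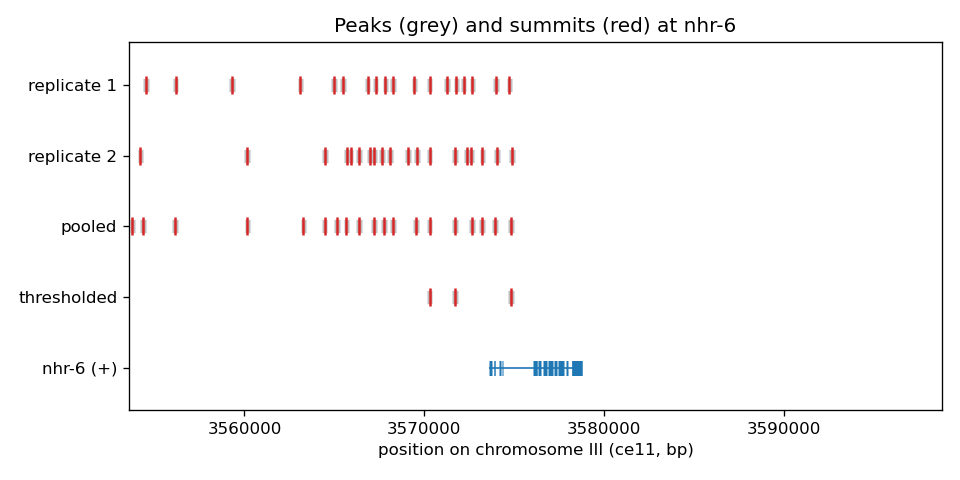
Peaks (grey) and summits (red) of each list from 20 kb upstream to 20 kb downstream of nhr-6 (blue, exons as boxes) on chromosome III of ce11, position in bp on the x axis. The thresholded list has 3 summits, at 3570288, 3571712 and 3574804, and no list has a summit between 3574857, in replicate 2, and the right edge.

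The 4 strongest thresholded summits all lay in 1 interval over egl-5 (WBGene00001174), a Hox gene, named here after its values were seen. The interval ran from 7814327 to 7816995 on chromosome III, 2669 bp wide, and egl-5 from 7814374 to 7817141 on the plus strand. Its summits had signals of 1433 (3′ untranslated region), 1302 (intron), 929.4 (intron) and 258.8 (coding exon), against 199.2 for the next strongest peak. No other thresholded peak was wider than 316 bp. Both replicates held the interval, with 4 summits reaching 907.8 in replicate 1 and 5 reaching 587.9 in replicate 2. Neither AAAGGTCA nor AGGTCA lay within 50 bp of any of the 4 summits. Without this interval the correlation of replicate signals had a rho of 0.28 and an r of 0.26.

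**Figure D5:**
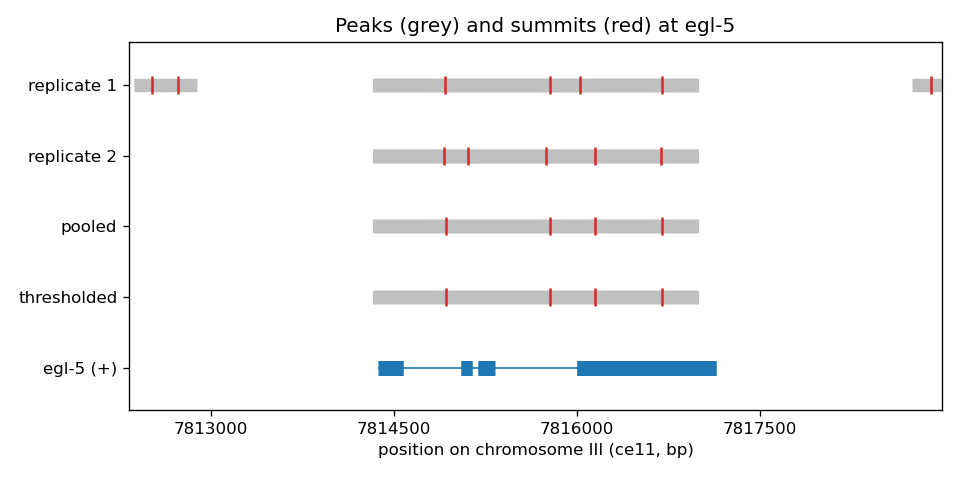
Peaks (grey) and summits (red) of each list at egl-5 (blue, exons as boxes) on chromosome III of ce11, position in bp on the x axis. A single interval, 2659 to 2669 bp wide depending on the list, covers nearly the whole gene in each list.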

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

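The comparison in this part was chosen after its values had been seen. The relaxed list of replicate 1 held 28 peaks on the mitochondrial chromosome, which no comparison used, where the list of replicate 2 held 0; their signals reached 514.2 (rank 4 of 26801) and they covered 51.6% of that chromosome, and the pooled and thresholded lists held 0.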

How the results depend on the processing

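The tests over all pooled peaks at the highest q, against sites of the same base composition, with genes matched on promoter GC and without the egl-5 region were chosen after the main values had been seen. Of the values that answer a comparison, 70 kept their direction and side of the threshold, stayed within their interval or, for counts, stayed within 1.5 times the main count, 3 moved out of their interval, 6 newly passed and 1 reversed. The counts went from 13 gene lists to between 11 and 14, not always the same lists, and from 1122 6-mers to 807 and 847. The share of thresholded peaks among the strongest of each replicate was 71.9% for replicate 1 and 72.7% for replicate 2 when summits had to lie within 100 bp, a stricter rule by construction, and rho between replicates was 0.51 over all matched relaxed peaks. X density passed when counted per gene (ratio 1.43). The NR4A site passed with a window of 100 bp (ratio 2.64), as the 6-base core (1.68), with each replicate left out (3.82 to 4.36) and over all pooled peaks at the highest q (4.24). It did not pass under the others, among them the window of 25 bp (1.56), relaxed peaks outside the list as background (1.49) and its rank among 840 sites of the same base composition, of which 37 had a higher ratio and whose median it exceeded 3.10-fold. Its difference by signal reversed with the 6-base core (-0.441 percentage points). Among single lists and classes, spermatheca genes reversed with the window of 2000 bp (odds ratio 1.16) and antisense RNA genes among the 1360 strongest peaks (fold 1.63) and with each replicate left out (1.11 to 1.37), none of them past a threshold in either direction. Among the noncoding classes other than tRNA, snRNA and snoRNA, the lists that passed in any setting and the spermatheca, nuclear receptor and pan-neuronal lists, 7 values no longer passed, 6 newly passed (core histones, cytochrome P450 and lincRNA genes) and 130 did not change in direction or side. The cause was not tested for any of these. The nhr-6 locus was not run in ce10, because the annotation is of ce11. No paired analysis was possible because there is 1 group. Read depth, which limits weak peaks, is unknown.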

Other observations

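The tests on gene name families, on the ends, introns and surroundings of the egl-5 region and on chance spacing at nhr-6 were chosen after those values had been seen, and those on promoter GC and on mapping at nhr-6 after the patterns had been seen but before their own values. Among 240 families of genes that share a name prefix and have at least 8 members, 30 differed from other genes in promoter peaks (Fisher's exact test, adjusted p under 0.05), 16 with more and 14 with fewer. Beyond the ribosomal proteins, SR splicing factor genes carried one in 6 of 8 cases (75%, exact adjusted p = 0.000824), led by rsp-1 and rsp-2, which share a peak of signal 78.02. Nucleoporin genes carried one in 10 of 26 (38.5%, exact adjusted p = 0.00347), led by npp-14 (64.2), and mitochondrial ribosomal proteins of the large subunit in 13 of 41 (31.7%, exact adjusted p = 0.00349), led by mrpl-49 (102.6). Vacuolar sorting genes carried one in 12 of 31 (38.7%, exact adjusted p = 0.000871), led by vps-60 (101.7), translation initiation factors in 8 of 25 (32%, exact adjusted p = 0.0290) and RNA polymerase II subunits of the rpb family in 5 of 11 (45.5%, exact adjusted p = 0.0294). The other families with more were rpl, rps, rpn, vha and cct, which overlap the lists of the report, and lin (13 of 47), tag (17 of 57), pqn (14 of 56), rbm (6 of 13) and lec (5 of 12), of which lin names a phenotype, tag a provisional name and pqn a sequence composition. Those with fewer were the chemoreceptor families str, srw, srh, srx, srbc, srd and srt, and clec, fbxa, fbxb, col, nlp, lgc and irld, the last 2 with 0 of 56 genes each.

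The wide region over egl-5 is the strongest signal in the data. Carry-over of spliced transcript or its cDNA is argued against, since 2 of the 4 pooled summits of the region lie in introns. Unspliced transcript holds the introns, so its carry-over stays open. Carry-over of a genomic DNA fragment of the gene stays open: both ends lie within 151 bases of the annotated ends in both replicates, but these ends prompted the idea and cannot count in its favour. For a long multi-copy transgene around the gene, the 15 kb on each side held 10 relaxed pooled peaks. That lies between the median (8) and the 95th percentile (20) of 30 kb stretches, and a peak count does not measure copy number. The signals of these peaks were 4.58 to 24.8, against 258.8 to 1433 in the region. They argue against a long transgene that raised signal evenly along its length, while one hardly longer than the gene stays open. No biological explanation was tested, and binding of NHR-6 there is not excluded.

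Peaks at ribosomal protein promoters may reflect properties of those promoters and not the factor. Promoter GC content as the whole cause is argued against by a fold of 6.26 over genes matched on it (adjusted permutation p = 0.000755). The length of the upstream intergenic region as the whole cause is argued against by a fold of 5.37 (adjusted permutation p = 0.00136). Over all other genes the fold was 7.98 (7.02 to 8.66, from the Wilson interval of the share). The matched folds were lower, with ranges that reached 6.79 for GC content and 5.83 for length. All of these folds share the same count of genes with a peak, so their ranges do not test the drop. The matched sets could also include genes of the list itself, which lowers the matched folds. Whether each property accounts for part of the excess stays open. A single replicate as the source is argued against by odds ratios of 38.1 and 24.9 in the strongest peaks of replicates 2 and 1 alone. Whether promoters of highly transcribed genes gain peaks with any tagged protein stays open, since no other factor or untagged strain was analysed here, and no biological explanation was tested.

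From the intron of nhr-6 no pooled relaxed summit occurs for 29596 bp, while the 10 kb upstream of the gene hold 12, a density met in 1.08% of 10 kb stretches. Sequence that short reads cannot map uniquely is argued against, as 0.626% of the 31-mers of the stretch occur elsewhere. Chance spacing stays open: 16.6% of the genome lies in stretches at least as long without a pooled summit, though for the summits of the replicates and the pooled list together it is 3.81%. An edge of the transgene insert was not tested, as its extent is not given in the sources used here, nor was a biological explanation.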
